A study of Mus musculus with 6 samples.

How the data were processed

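Total RNA from spheres of mouse mammary tumors was labelled with Cy3 and hybridised to 6 single-colour Agilent arrays, 3 for tumors of mice heterozygous for FRS2beta (hetero) and 3 for tumors of knockout mice, per the labels. The spheres were grown in DMEM/F12 with B27 supplement, EGF at 20 ng/mL, bFGF at 20 ng/mL and heparin at 2 mg/mL, per the labels' protocols. The labels number 3 replicates per genotype and do not say whether these came from separate animals, tumors or cultures. The p-values therefore measure only the spread between these samples, which may be technical. On 321 probes with several spots, a single spot varied between arrays of a genotype by a median SD of 0.042 on the log2 scale. Spots of a probe within an array varied by 0.066, so the spread between arrays was no larger than that within an array. Replicate numbers were taken from the labels.

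The scanner images were quantified with Agilent Feature Extraction 10.7.3.1, per the submitters' processing notes and the file headers. The deposited scanner files hold spot intensities on a linear scale, and the intensity used here is the processed signal, from which Feature Extraction had subtracted background and spatial trend, per the file headers. No scaling between arrays had been applied to these intensities. The series also has a deposited table of intensities for 46598 probes. Set against the scanner files, that table equals the processed signal divided by a constant for each array, within 1% for 100% of the probes spotted once, and the constants ran from 402 to 484. Its column medians were 0.161, 0.159 and 0.169 for hetero replicates 1 to 3 and 0.163, 0.159 and 0.159 for knockout replicates 1 to 3. Its scale is therefore linear and it is not centred by gene, while the rule by which its probes were chosen is not given in the sources used here.

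Each array held 62976 spots, of which 3671 were controls and were left out, as were 102 to 129 spots per array that carried an outlier flag. Spots of the same probe were averaged on the log2 scale, giving 55681 distinct probes, 27 of which were lost to outlier flags. No spot was saturated. The array's gene names are those of its design, so probes were named through their RefSeq accession with a table of mouse genes on assembly GRCm38.p6, from which names and gene order but no coordinates were taken, because the array header names assembly mm9. A symbol was found for 27235 probes, covering 20660 genes, and 28446 probes, 16194 of them designed to chromosome intervals, stayed without a symbol and outside the gene comparison.

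The log2 processed signal was scaled by subtracting the 75th percentile of each array over its probes. Probes called well above background by Feature Extraction on at least 3 of the 6 arrays were kept, 35427 in all, and each gene was represented by its brightest kept probe, which left 15838 genes. The genotypes were compared with lmFit and eBayes of limma 3.58.1 in R 4.3.3 with no covariate, and p-values were adjusted by the Benjamini-Hochberg method over the genes tested, with a threshold of 0.05. Fold changes are knockout over hetero. Where a gene was not well above background on any array of a group, its fold is a bound, printed as "at least N-fold". The bound sets the bright group's mean against the dim group's mean of, per array, the higher of the gene's own value and the lowest signal among probes well above background. A second probe of the gene was called in the opposite direction for 103 of the called genes.

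Before the data were examined, 37 gene lists were fixed for mammary epithelium, receptor signalling, sphere culture and other cell types a tumor could bring, and 36 had at least 5 members tested. Of their 710 genes, 709 matched a symbol and 651 were tested. Lists were compared with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry, each adjusted over the 36 lists. The genes named were also fixed by rule: Frs3, Frs2, Erbb2, Egfr, Fgfr1, Fgfr2, Igf1 and Cxcl12 always, then the 12 largest rises and the 12 largest falls among called genes with a symbol whose groups did not overlap and whose brighter group was well above background on its 3 arrays, and in each list up to 4 tested members with the smallest p. Genes named beyond this rule are said to be so, and the values of 2 genes that the rule takes are not reported here.

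The number of arrays, 3 per group, limits the precision. All 6 arrays lay on 1 slide and were scanned in 1 run, so a slide or scan block could not be fitted. Slide row 1 held replicates 1 and 2 of both genotypes and row 2 held replicate 3 of both. Each of the 4 slide columns held a single genotype.

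The fit was checked on simulated arrays for the knockout against hetero comparison, with the real means and spreads of 15838 genes and 50 genes changed at each of 4 sizes. It recovered 38.0% of genes changed by 0.25 on the log2 scale, 80.0% at 0.5, 86.0% at 1 and 98.0% at 2, and 6 of its 157 calls were unchanged genes. The real fit called 9563 genes, which makes the adjusted p threshold less strict there, so these recovery rates do not carry over to it. With independent errors and no change, camera gave an unadjusted p below the threshold for 2.72% of lists and fry for 5%, over 50 simulated sets of the 36 lists.

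Alternatives fixed beforehand were normexp background correction with an offset of 50, quantile and median scaling, no filter, a filter on all 6 arrays, a floor, the mean of a gene's probes, outlier spots kept, eBayes with trend and robust options, array weights, the deposited table, a replicate block, each replicate left out in turn, every probe on its own, limma's treat against a fold of 1.2, camera with an estimated correlation and fry. Added after seeing the data were scaling to spike-in spots, slide row as a block, slide row 1 alone, slide column as a random block, and lists cleared of genes held by another list. The planned normexp on the mean spot signal was run on the median spot signal instead, because the mean signal is not among the columns of the files used here.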

Results

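Spheres, free-floating clusters of cells grown in serum-free medium with growth factors, were made from mammary tumors of mice heterozygous for FRS2beta (hetero) and of FRS2beta knockout mice. Their RNA was measured on 3 arrays per genotype. FRS2beta is an adaptor protein that docks on receptor tyrosine kinases, among them FGF and ErbB receptors, and is encoded by Frs3. The design holds a single comparison, which asks how expression in tumor spheres differs between the 2 genotypes. The 75th percentile of the processed signal was 404 to 416 on the hetero arrays and 465 to 487 on the knockout arrays. Of all probes, 60.4% to 61.3% were well above background on the hetero arrays and 60.5% to 69.6% on the knockout arrays. After scaling, arrays of the same genotype correlated at 0.995 to 0.998 across genes and arrays of different genotypes at 0.966 to 0.971. The first principal component, with 85.1% of the variance, separated the genotypes. These correlations are across genes, which are not independent replicates.

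Knockout spheres carried far more RNA of mammary epithelial genes and less RNA of macrophage, interferon and antigen presentation genes than hetero spheres, by gene lists that passed camera with a preset correlation and not with an estimated one (adjusted p = 0.0863, 0.0876, 0.104 and 0.158 with an estimated correlation). Among single genes, the largest rise was that of the casein gene Csn1s1, from a scaled log2 signal of -3.27 ± 0.05 to 3.05 ± 0.03 (SD, n = 3 each), a 79.9-fold difference. Fcgbp, a mucin-like secreted protein, rose 70.8-fold, the luminal transcription factor gene Foxa1 29.8-fold with 1 of 3 hetero arrays above background, and Ltf, the milk protein lactoferrin, 27.8-fold. Clca3a2 (30.2-fold), the carbonyl reductase Cbr2 (29.2-fold) and surfactant protein D, Sftpd (27.9-fold), rose to a similar extent. In hetero spheres 5 further genes were not well above background on any array, so that their rises are bounds: at least 25.6-fold for Itprid1, 23.5-fold for the transcription factor Tfap2b, 22.2-fold for the gap junction gene Gjb2, 18.0-fold for the ion channel Asic2 and 7.91-fold for the lipase Lipk. Among the falls, B3gat1, a glucuronyltransferase that makes the HNK-1 epitope, and the collagen gene Col6a5 were below background on all knockout arrays and at least 31.5-fold and 12.6-fold lower. Vitronectin, Vtn, was 18.1-fold lower, the angiotensin receptor Agtr1a 15.2-fold, Ly6h 13.6-fold, and Olfml1 and Tmeff2 9.82-fold and 9.77-fold. The macrophage lectin genes Clec10a and Mrc1 were 10.8-fold and 9.82-fold lower, Clec10a with 1 of 3 knockout arrays above background. Pira2, the fetal serum protein Afp and Arhgap30 fell to below background on the knockout arrays, by at least 3.28-fold, 3.39-fold and 4.15-fold. Genes given with a bound were ranked by fitted values that lie below background, so their rank is not measured. With normexp background correction the log2 changes of Fcgbp, Foxa1, Mrc1, Tmeff2 and Clec10a were 3.88, 2.71, -1.91, -1.90 and -1.36. Those of the 10 genes with a bound were below it (1.12 to 2.14 for the rises, -2.52 to -0.70 for the falls), so these bounds hold for the processed signal alone. The normexp offset of 50 is above the median processed signal of each array (31.1 to 38.1). It thus shrinks the folds of dim genes by construction, and a smaller normexp fold does not by itself count against a bound. Adjusted p for these 24 genes ran up to 0.000242, for Arhgap30.

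**Figure D1:**
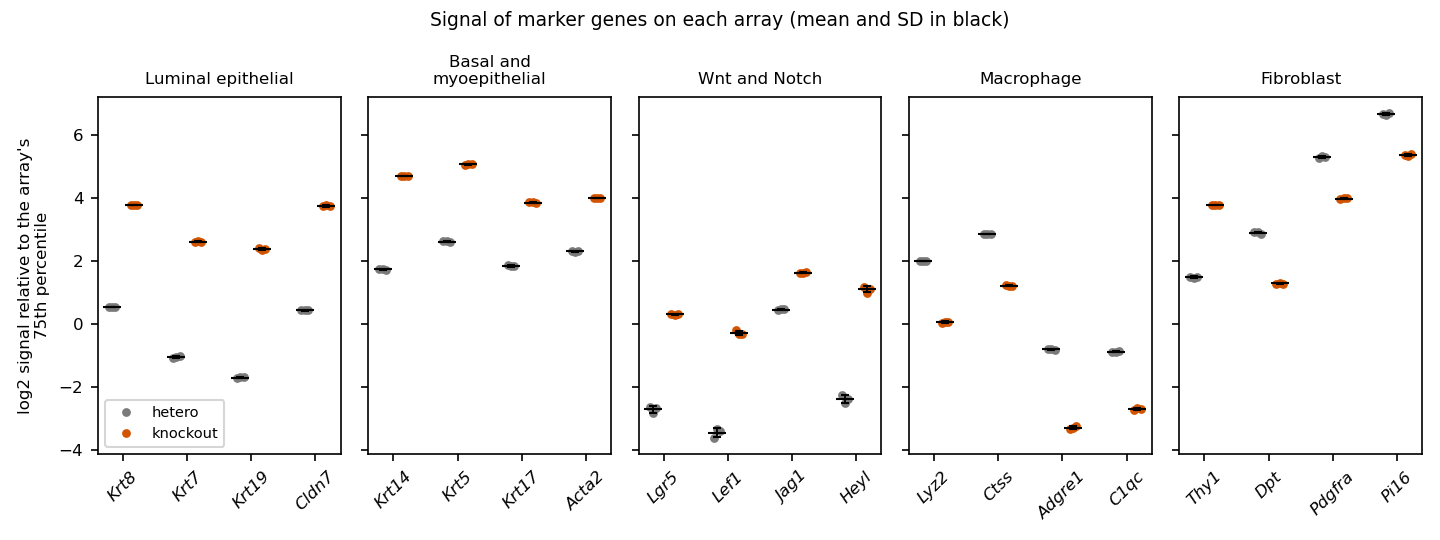
Scaled log2 signal (log2 signal relative to the array's 75th percentile, vertical axis) of 20 marker genes on each of the 3 hetero arrays (grey) and 3 knockout arrays (orange), with the mean and SD in black. Krt8, Krt7, Krt19 and Cldn7 lie higher on every knockout array and Lyz2, Ctss, Adgre1 and C1qc lower, with no overlap between genotypes.

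Of 15838 genes tested, 9563 (60.4%) passed an adjusted p of 0.05, 4403 higher and 5160 lower in knockout spheres. A fold of at least 2 was reached by 1600 of them, 1043 higher and 557 lower, and a fold of at least 4 by 478 higher and 133 lower. With normexp background correction 860 genes reached a fold of at least 2. The 2 genotypes did not overlap in 68.9% of genes, against 10% if genotype labels were given to the arrays at random. The replicates may be technical, so any difference between the 2 sets of samples, not genotype alone, could give such a share. The median standard error of a log2 fold change was 0.041, and most calls were smaller than 2-fold. Scaling to spike-in spots in place of the 75th percentile was an alternative added after seeing the data. It moved the median log2 fold change of all genes from -0.03 to 0.28 and changed the split to 1869 higher and 477 lower. This scaling adds 0.31 to every log2 fold change and raised the median standard error to 0.308, so that rises lost their call through the wider spread between arrays, and falls through this spread and the shift. Falls smaller than 0.31 changed sign by construction. The sign of small falls thus depends on the scaling, and all changes are relative to the other genes of the array.

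Frs3 itself was hardly detected. Its single probe on the array, for transcript NM_144939, had a scaled log2 signal of -5.99 ± 1.33 in hetero spheres and -7.73 ± 0.32 in knockout spheres (SD, n = 3 each). It was well above background on 1 of the 3 hetero arrays and on 0 of the 3 knockout arrays. Because the hetero mean lay below the lowest signals counted as above background, no fold is given, and the targeted gene does not check the genotype labels here. Whether the probe lies in the deleted part of the gene is not given in the sources used here.

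All 19 tested luminal keratin and epithelial adhesion genes were higher in knockout spheres, with a median log2 fold change of 3.33, or 10.1-fold (camera adjusted p = 1.26e-13, adjusted p = 0.0863 with an estimated correlation). The simple-epithelial keratins Krt8, Krt7 and Krt19 rose by 3.25 ± 0.02, 3.65 ± 0.02 and 4.08 ± 0.03 log2 units (SE), and the tight junction gene Cldn7 by 3.31 ± 0.02. In 2 of the 19 genes the hetero signal was a bound, and with these at their bound the median was 3.33 as well. Markers of luminal progenitors, the cells that give rise to the milk-secreting lineage, rose in 14 of 18 genes and fell in 4, with a median of 0.91 (camera adjusted p = 0.00018, adjusted p = 0.0863 with an estimated correlation). Tspan8 rose by 3.46 ± 0.02, the transcription factor Sox10 by 3.05 ± 0.03, the iron-binding lipocalin Lcn2 by 2.38 ± 0.03 and the aldehyde dehydrogenase Aldh1a3 by 4.19 ± 0.07. With 1 member at its bound, this median was 0.79, and with normexp 0.60. Hormone-sensing luminal markers went both ways, 9 of 13 higher and 2 lower (median 0.67, camera adjusted p = 0.0253, adjusted p = 0.16 with an estimated correlation). Gata3, a luminal transcription factor, rose by 3.04 ± 0.08 and Prom1 by 2.19 ± 0.02, while Ly6a fell by 1.99 ± 0.02 and Tnfsf11, the RANK ligand, by 2.15 ± 0.03. The hormone-sensing median was 0.39 without the filter and 0.43 with normexp. This list's call was lost when probes had to be above background on all 6 arrays (median 0.11, adjusted p = 0.0758) and when a gene's probes were averaged (adjusted p = 0.0684), and adjusted p over the settings with the preset correlation ran from 0.000112 to 0.0758. Milk protein genes rose in 5 of 10 and fell in 1 (median 0.30, camera adjusted p = 0.0445, adjusted p = 0.251 with an estimated correlation). They were led by Csn1s1, by Muc15, at least 6.47-fold higher, and by the kappa-casein gene Csn3, at least 1.92-fold higher, while Xdh fell by 0.74 ± 0.03. With normexp Muc15 and Csn3 lay below these bounds (0.76 and 0.31 log2 units). The list median was 0.45 with quantile scaling, 0.19 with normexp and 0.14 with probes above background on all 6 arrays. The milk list call was lost under 6 of these settings, among them the fit without hetero replicate 2 (adjusted p = 0.0669), and adjusted p over the settings with the preset correlation ran from 1.77e-06 to 0.254.

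Basal and stratified epithelial genes were higher as well. Of 19 basal and myoepithelial markers, 12 rose and 5 fell, with a median of 1.01 (camera adjusted p = 0.00159, adjusted p = 0.0876 with an estimated correlation). The basal keratins Krt14, Krt5 and Krt17 rose by 2.97 ± 0.02, 2.45 ± 0.02 and 2.01 ± 0.02, and the contractile gene Acta2, smooth muscle actin, by 1.69 ± 0.02. Squamous and keratinization genes rose in 10 of 15 and fell in 1 (median 1.36, camera adjusted p = 0.000883, adjusted p = 0.0876 with an estimated correlation). Among them, Krt6a rose by 3.12 ± 0.08, Krt6b by 2.91 ± 0.03, Krt13 by 2.33 ± 0.05 and involucrin, Ivl, by 1.36 ± 0.03. The squamous median was 0.61 with normexp (Krt6a 2.00), 0.69 without the filter and 0.90 with probes above background on all 6 arrays, and the list passed in each. Genes that have been tied to tumor-initiating cells rose in 16 of 21 and fell in 4 (median 0.41, camera adjusted p = 4.8e-05, adjusted p = 0.0876 with an estimated correlation). The surface markers Cd24a, Thy1 and Prom1 rose by 3.44 ± 0.03, 2.29 ± 0.02 and 2.19 ± 0.02 and the intermediate filament gene Nes by 1.94 ± 0.03. Of the 21 members, 12 also stand in another of the lists. EMT and mesenchymal genes went both ways, 6 of 20 higher and 10 lower, and did not pass as a list (median -0.10, camera adjusted p = 0.462). Fap rose by 0.59 ± 0.03, and Mmp2 and Tgfbi fell by 0.89 ± 0.03 and 0.98 ± 0.03.

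**Figure D2:**
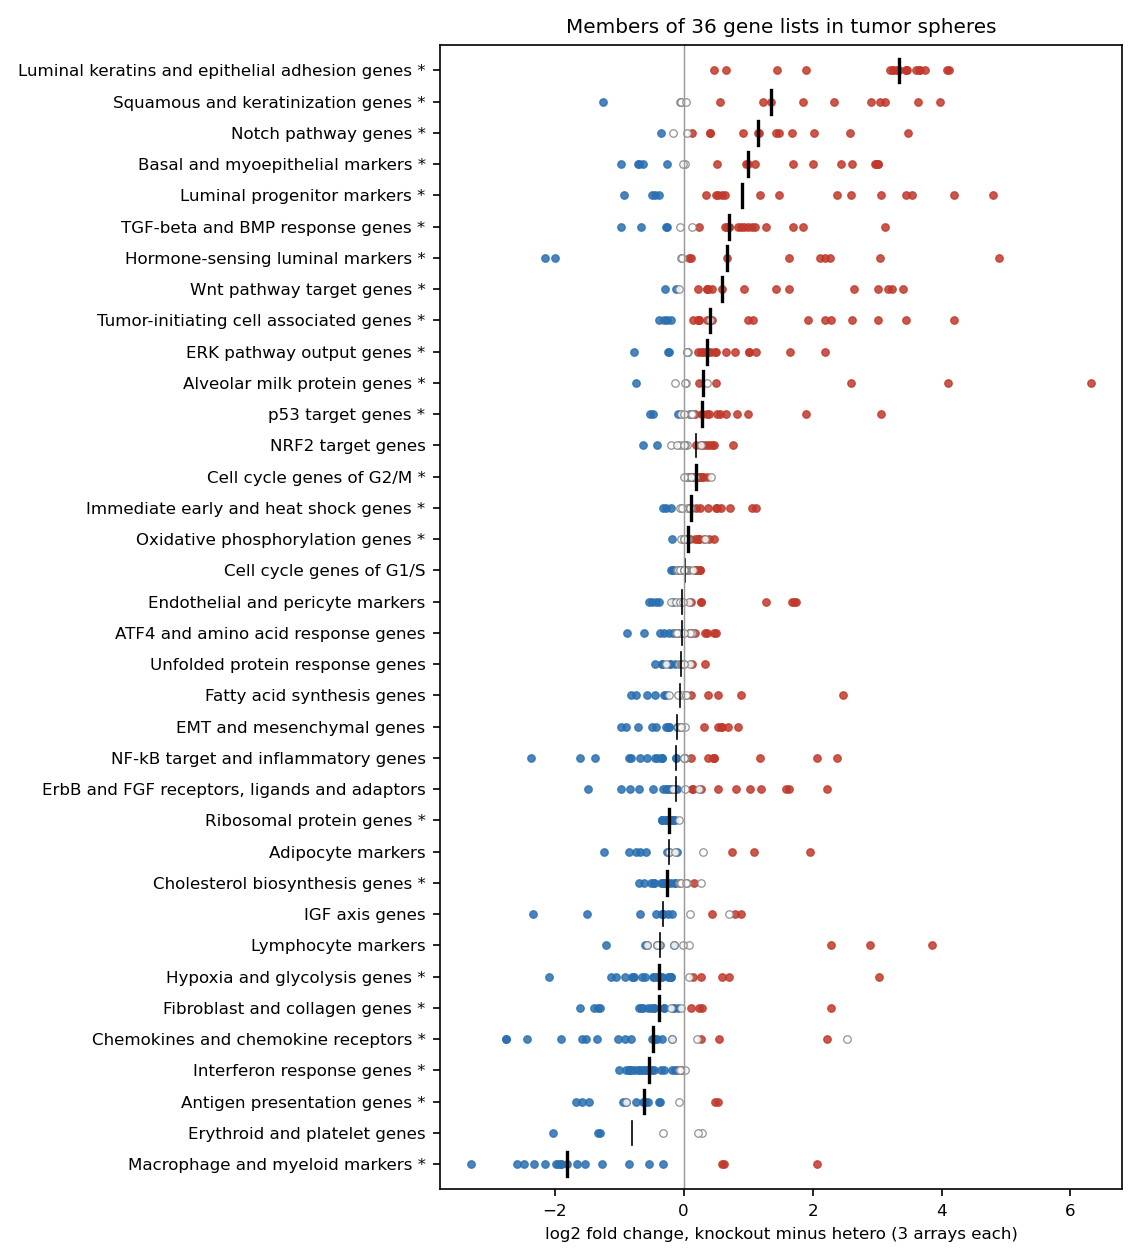
Log2 fold change (knockout minus hetero, 3 arrays each, horizontal axis) of each tested member of 36 gene lists, ordered by the list's median (black bar). Red and blue points passed an adjusted p of 0.05 and open points did not, and a star and a thick bar mark the 23 lists past camera's adjusted p with a preset correlation, from luminal keratins (median 3.33) to macrophage markers (-1.81). The ribosomal protein list changes direction with quantile or spike-in scaling and the cholesterol list with spike-in scaling.

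Genes of the Wnt, Notch and TGF-beta pathways, which act in epithelial stem and progenitor cells, were mostly higher in knockout spheres, beside the epithelial median of 3.33. Wnt target genes rose in 14 of 17 and fell in 2 (median 0.59, camera adjusted p = 5.53e-05, adjusted p = 0.0876 with an estimated correlation). The R-spondin receptor Lgr5 rose by 3.02 ± 0.06, the transcription factor Lef1 by 3.17 ± 0.08, and the Wnt inhibitors Wif1 and Apcdd1 by 3.40 ± 0.10 and 1.64 ± 0.05. The Wnt median was 0.38 with normexp (Lef1 2.06, Wif1 1.86) and 0.94 when probes were averaged, and the list passed in both. Notch pathway genes rose in 12 of 15 and fell in 1 (median 1.16, camera adjusted p = 0.000172, adjusted p = 0.0863 with an estimated correlation). With normexp background correction the median was 0.27, and the list still passed. The ligands Jag1 and Dll1 rose by 1.17 ± 0.02 and 1.44 ± 0.03, the receptor Notch3 by 1.69 ± 0.03 and the effector Heyl by 3.47 ± 0.08. TGF-beta and BMP response genes rose in 15 of 21 and fell in 4 (median 0.71, camera adjusted p = 0.000157, adjusted p = 0.0863 with an estimated correlation). Id4, a target of BMP signalling, rose by 3.12 ± 0.06, Ccn2 by 1.86 ± 0.03, the activin subunit Inhba by 1.70 ± 0.02 and Tgfb1 by 1.01 ± 0.02.

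Receptors, ligands and adaptors of the ErbB and FGF families, the receptors on which FRS2 proteins dock, moved in both directions. Of 26 tested, 10 rose and 13 fell, and the list did not pass (camera adjusted p = 0.964), with a median of -0.12 and a mean of 0.14. The paralog Frs2 differed by -0.11 ± 0.03 (SE, adjusted p = 0.035). That call was lost under quantile or median scaling, without the filter, with normexp, with replicate numbers as a block (adjusted p = 0.0716), and without hetero replicate 1 or 2 or any of the 3 knockout replicates (adjusted p 0.0779 to 0.0947). With spike-in scaling its sign turned, and over 22 refits its adjusted p ran from 0.00717 to 0.71. Erbb2 differed by 0.02 ± 0.03 (adjusted p = 0.625) and Fgfr2 by -0.16 ± 0.10 (adjusted p = 0.204), both short of the threshold. Egfr fell by 0.69 ± 0.02 and Fgfr1 by 0.25 ± 0.03. Under spike-in scaling neither passed and Fgfr1 changed sign, and under quantile scaling Fgfr1 did not pass (adjusted p = 0.0561, at most 0.919 over the 22 refits). The EGF-family ligand gene Hbegf rose by 2.23 ± 0.04, and the FGF ligand genes Fgf1 and Fgf7 fell by 1.49 ± 0.06 (0.89 when probes were averaged) and 0.83 ± 0.03. Output genes of the ERK pathway rose in 16 of 22 and fell in 3, beside the epithelial median of 3.33 (median 0.37, camera adjusted p = 0.000157, adjusted p = 0.0863 with an estimated correlation). The receptor gene Epha2 rose by 2.19 ± 0.02, Fos by 1.12 ± 0.03, the phosphatase Dusp4 by 1.02 ± 0.04 and Plaur by 1.01 ± 0.03. Of 15 IGF axis genes, 3 rose and 10 fell, and the list did not pass (median -0.31, camera adjusted p = 0.0748). Igf1 fell 2.83-fold (adjusted p = 6.05e-07). The binding protein gene Igfbp4 fell by 2.34 ± 0.06 log2 units, Htra1 by 0.67 ± 0.03 and Igf2r by 0.31 ± 0.02.

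Interferon response genes were lower in knockout spheres: 21 of 26 fell and 0 rose, with a median of -0.54 (camera adjusted p = 6.0e-06, adjusted p = 0.104 with an estimated correlation). Ifit3 fell by 0.90 ± 0.03, the signal transducer Stat2 by 0.69 ± 0.03, and Xaf1 and Zbp1 by 0.59 ± 0.03 and 0.57 ± 0.02. With spike-in scaling the list still passed, but these 4 genes did not (adjusted p 0.242 to 0.650). Antigen presentation genes fell in 12 of 16 and rose in 2 (median -0.62, camera adjusted p = 0.000729, adjusted p = 0.158 with an estimated correlation). The MHC class I genes H2-D1 and H2-K1 fell by 1.57 ± 0.02 and 1.47 ± 0.02. The immunoproteasome genes Psmb9 and Psmb8 fell by 1.66 ± 0.03 and 0.94 ± 0.03. Chemokines and their receptors fell in 16 of 22 and rose in 3 (median -0.47, camera adjusted p = 0.00159, adjusted p = 0.0876 with an estimated correlation). Ccl3 and Ccl4 both fell by 2.76 (SE 0.04 and 0.05) and Cxcl5 fell by 1.91 ± 0.04. The stromal chemokine gene Cxcl12 fell by 1.52 ± 0.03 (2.60 with normexp, 1.21 to 2.60 over 22 refits), while Cxcl14 rose by 2.22 ± 0.03. Cxcl12 has 2 tested probes, and the cause of its larger normexp fold was not tested. NF-kB target and inflammatory genes split, 8 of 26 higher and 14 lower, and did not pass as a list (median -0.12, camera adjusted p = 0.462). Lcn2 and the prostaglandin synthase Ptgs2 rose by 2.38 ± 0.03 and 2.06 ± 0.03. The acute-phase gene Saa3 and the adhesion gene Vcam1 fell by 2.38 ± 0.03 and 1.38 ± 0.03. Macrophage markers moved with these groups, with a median of -1.81.

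Macrophage and myeloid markers fell in 16 of 19 genes and rose in 3 (median -1.81, or 3.52-fold lower, camera adjusted p = 4.8e-05, adjusted p = 0.0876 with an estimated correlation). The macrophage surface marker Adgre1 fell by 2.48 ± 0.03 (1.54 with normexp), lysozyme, Lyz2, by 1.95 ± 0.02, the complement gene C1qc by 1.81 ± 0.02 and cathepsin S, Ctss, by 1.65 ± 0.02. The 3 that rose were Cd14, S100a8 and S100a9, named here after their values were seen. Fibroblast and collagen genes fell in 16 of 22 and rose in 4, by less (median -0.38, camera adjusted p = 0.00129, adjusted p = 0.0876 with an estimated correlation). Dpt, Pdgfra and Pi16 fell by 1.61 ± 0.02, 1.32 ± 0.03 and 1.30 ± 0.03, and Thy1 rose by 2.29 ± 0.02. The fibroblast median was -0.14 with quantile scaling. With spike-in scaling the fibroblast list missed the threshold (adjusted p = 0.0523, from 0.000666 to 0.0523 over the settings with the preset correlation). Endothelial and pericyte markers split, 7 of 18 higher and 5 lower (median -0.02, mean 0.26, camera direction up, camera adjusted p = 0.389). Cspg4, Plvap, Notch3 and Flt1 rose by 1.74 ± 0.03, 1.71 ± 0.03, 1.69 ± 0.03 and 1.28 ± 0.03. Lymphocyte markers did not pass as a list (3 of 15 higher, 6 lower, median -0.37, mean 0.29, camera adjusted p = 0.619). Neither did adipocyte markers (3 of 14 higher, 8 lower, median -0.23, camera adjusted p = 0.418) or erythroid and platelet genes (0 of 6 higher, 3 lower, median -0.81, camera adjusted p = 0.214, passing with spike-in scaling at 0.0329). The B-cell gene Ms4a1 was at least 5.3-fold higher, Klrb1c rose by 2.89 ± 0.11 and Thy1 by the value above, and Lck fell by 0.41 ± 0.02. With normexp Ms4a1 lay below its bound (0.62 log2 units) and Klrb1c at 1.04. Among adipocyte genes, Lpl and Pparg fell by 1.24 ± 0.03 and 0.68 ± 0.02, and Cidea and Slc2a4 rose by 1.96 ± 0.07 and 1.10 ± 0.04 (0.82 and 0.72 with normexp). The platelet genes Pf4 and Ppbp fell by 2.02 ± 0.03 and 1.29 ± 0.08, Ppbp by 0.53 with normexp. Of 5 sex-linked genes, Xist alone was tested, and it differed by -0.27 ± 0.03 with a sign that turned under spike-in scaling.

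Hypoxia and glycolysis genes fell in 20 of 26 and rose in 5 (median -0.38, camera adjusted p = 0.00159, adjusted p = 0.0876 with an estimated correlation). With spike-in scaling the list missed the threshold (adjusted p = 0.0935, from 0.000900 to 0.0935 over the settings with the preset correlation). With quantile scaling its median was -0.20. Adm fell by 2.09 ± 0.03, the pyruvate dehydrogenase kinase Pdk1 by 1.12 ± 0.03 and Ndrg1 by 1.05 ± 0.03, whereas the carbonic anhydrase Car12 rose by 3.03 ± 0.03. Cholesterol biosynthesis genes were lower in 17 of 24 and higher in 1 (median -0.26, camera adjusted p = 0.000873, adjusted p = 0.0972 with an estimated correlation), a direction that turned with spike-in scaling to 0.05. Tm7sf2, Stard4 and Hmgcs1 fell by 0.62 ± 0.03, 0.70 ± 0.04 and 0.46 ± 0.03, and the regulator Srebf2 by 0.32 ± 0.02. Ribosomal protein genes were lower in 23 of 24 (median -0.22, camera adjusted p = 4.87e-05, adjusted p = 0.0876 with an estimated correlation), a direction that turned to 0.01 with quantile and 0.09 with spike-in scaling. Fatty acid synthesis genes split 5 higher and 6 lower of 16 (median -0.06, mean 0.06, camera adjusted p = 0.964). Thrsp and the desaturase Scd1 rose by 2.47 ± 0.04 (0.98 with normexp) and 0.89 ± 0.03, and Elovl6 and Acsl1 fell by 0.81 ± 0.03 and 0.74 ± 0.03.

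Mitotic genes of G2/M rose slightly in 16 of 22, and 0 fell (median 0.19, or 1.14-fold, camera adjusted p = 0.000532, adjusted p = 0.0876 with an estimated correlation). Ube2c, Cenpe and Foxm1 rose by 0.30 ± 0.03, 0.29 ± 0.04 and 0.25 ± 0.04 and Mki67 by 0.14 ± 0.02. With spike-in scaling these 4 folds were larger (0.45 to 0.61) and did not pass because of the wider spread (adjusted p 0.211 to 0.409). Mki67 also missed the threshold with median scaling (0.16, adjusted p = 0.0698) and Foxm1 when probes were averaged (0.18, adjusted p = 0.202). Genes of G1/S did not pass as a list (6 of 23 higher, 3 lower, median 0.02, camera adjusted p = 0.418). p53 target genes rose in 12 of 21 and fell in 3, beside the epithelial median of 3.33 (median 0.28, camera adjusted p = 0.000812, adjusted p = 0.0876 with an estimated correlation). Perp, which also takes part in desmosomes, rose by 3.06 ± 0.04, and the apoptosis gene Pmaip1 by 1.90 ± 0.04. Immediate early and heat shock genes rose in 11 of 20 and fell in 3 (median 0.12, camera adjusted p = 0.00749, adjusted p = 0.16 with an estimated correlation). With quantile scaling the median was 0.19. Hspb1 rose by 1.06 ± 0.02 and Egr1 by 0.50 ± 0.03. Oxidative phosphorylation genes rose in 10 of 21 and fell in 1 by small amounts (median 0.07, camera adjusted p = 0.00716, adjusted p = 0.111 with an estimated correlation). Cycs and Ndufa4 rose by 0.46 ± 0.03 and 0.39 ± 0.03. This median was 0.24 with quantile scaling, 0.11 with normexp and 0.05 without hetero replicate 1. The G2/M, p53, immediate early and oxidative phosphorylation lists missed the threshold with spike-in scaling (adjusted p 0.0594 to 0.705), with medians that were larger (0.50, 0.59, 0.43 and 0.39). NRF2 target genes did not pass (8 of 17 higher, 2 lower, median 0.19, camera adjusted p = 0.0727), though they did with quantile scaling (adjusted p = 0.0202), without the filter (0.0382) and with normexp (0.0457, from 0.0202 to 0.728 over the settings with the preset correlation). Unfolded protein response genes (2 of 18 higher, 6 lower, median -0.04, camera adjusted p = 0.257) did not pass. ATF4 and amino acid response genes did not pass either (8 of 23 higher, 7 lower, median -0.03, mean -0.03, camera direction up, camera adjusted p = 0.964).

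In all, 23 of the 36 lists passed with the preset correlation, 15 higher and 8 lower. With an estimated correlation 0 passed camera, where the lowest adjusted p was 0.0863. In several lists the estimated correlation lay below the preset 0.01, so a larger correlation was not what lost their call. These include ERK output (-0.003), basal (-0.007), TGF-beta (-0.015), luminal progenitor (-0.026) and Notch genes (-0.061). For ERK output genes the unadjusted camera p was 3.5e-05 with the preset and 0.010 with the estimated correlation. By fry 34 passed, which tests whether a list's genes move on balance in a direction and not whether they move more than other genes. Adjusted over the list alone, the counts of higher and lower members were the same in 27 lists. They changed to 11 and 13 for ErbB and FGF genes, 4 and 10 for the IGF axis, 6 and 20 for hypoxia, 9 and 8 for ATF4 and 9 and 2 for NRF2. They changed to 15 and 5 for TGF-beta, 7 and 6 for endothelial markers, 0 and 4 for erythroid genes and 12 and 3 for immediate early genes. Within slide row 1 and slide row 2 the epithelial list had medians of 3.35 and 3.33 and the macrophage list -1.81 and -1.83, row 2 holding 1 array per genotype. With spike-in scaling the calls of Fgf7, Htra1, Xdh, Mmp2, Tgfbi, Ndrg1, Pdk1, Tm7sf2, Stard4, Hmgcs1, Srebf2, Elovl6, Acsl1, Psmb8 and Pparg were also lost, with folds from -0.81 to -0.01 (adjusted p 0.0568 to 0.986). Those of Cycs, Ndufa4 and Egr1 were lost with larger folds of 0.78, 0.71 and 0.82 (adjusted p 0.0534 to 0.119).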

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

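Probes that carry no gene symbol were left out of the comparison of genes, and many of them differed between the genotypes, more of them lower than higher in knockout spheres. Their test was chosen after the gene results were seen. Of 14766 such probes that passed the filter on dim probes, 1256 were higher and 3100 lower at an adjusted p under the threshold (limma, adjusted over these probes). Of the 15838 genes tested, 4403 were higher and 5160 lower, so rises were a smaller share among these probes than among genes. Among the 7930 designed to chromosome intervals, 148 were at least 2-fold higher and 98 at least 2-fold lower. The interval probes with the largest rises among those above background on all 6 arrays, given on mouse assembly mm9 as the array header names it, lay on chromosome 1 from 195332659 to 195335997 (log2 fold change 3.42 ± 0.04 SE), on chromosome 4 from 88583425 to 88584070 (2.47 ± 0.11) and on chromosome 13 from 28551902 to 28975446 (2.44 ± 0.27). The interval probe with the largest fall by the same rule, on chromosome 10 from 66383049 to 66386347, fell by 3.96 ± 0.14. Which transcripts these intervals hold was not examined, because no annotation of that assembly was used here, and no explanation was tested. Other scalings were not compared for the probes without a symbol. Olfactory receptor genes also leaned lower, with 47 lower and 5 higher of 216 tested. Their median turned from -0.23 to 0.08 with spike-in scaling. The excess of falls among probes without a symbol may likewise depend on the scaling.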

How the results depend on the processing

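Alternatives added after seeing the data were normexp on the median signal, spike-in scaling, slide row as a block or alone, slide column as a random block, and lists without shared genes. Values are log2 fold changes of genes or list medians, and the cause of each change was not tested except where stated. The total of called genes was 7088 to 10821 under the settings that moved it by less than 1.5 times, and 8564 to 8952 with a replicate left out. The count of 10821 came from slide column as a random block, where the estimated correlation within a column was -0.405. Each column held a single genotype, so a negative value there can raise the number of calls. The total was 2346 with spike-in scaling (1869 higher, 477 lower), 3804 with treat against a fold of 1.2 (1939 higher, 1865 lower) and 16640 probes when every probe was tested on its own. Genes with at least 2-fold changes numbered 860 with normexp and 1171 to 1855 elsewhere, and lists past the threshold 0 with an estimated correlation and 16 to 34 elsewhere. With replicate numbers as a block, 8511 genes passed (3932 higher, 4579 lower). The deviations of arrays with equal numbers had correlations across genes of -0.115 to -0.006, so these arrays did not deviate in the same direction. Arrays of equal number lay in neighbouring columns of a slide row, and whether they were handled as pairs is not known. Over the 21 settings that refitted the lists with the preset correlation and the 22 that refitted the genes, 721 list results and 3535 results of named genes kept their direction and their side of the threshold, 14 and 63 lost the call, 4 and 8 gained it, and 17 and 9 changed sign. Values moved by over 1.5 times for 31 named genes and 12 lists with normexp, 7 and 13 with quantile scaling and 54 and 28 with the spike-in shift. The normexp offset shrinks the folds of dim genes by construction. With an estimated correlation all 23 list calls were lost, also in lists whose estimate lay below the preset. With quantile scaling, sign changes were Rpl32 0.0103, unfolded protein response 0.0167, ATF4 0.0734 and ribosomal genes 0.00815, and with normexp ATF4 0.00962. Spike-in scaling adds 0.31 to every log2 fold, so its sign changes follow from this shift, and its median SE was 0.308. With it, genes that changed sign were Frs2 0.205, Fgfr1 0.0611, Fgfr2 0.155, Igf2r 0.000516, E2f1 0.122, Rpl32 0.0423 and Xist 0.0462. Lists that did so were NF-kB 0.197, ErbB and FGF 0.191, IGF axis 0.000516, EMT 0.216, cholesterol 0.0536, fatty acid 0.253, unfolded protein response 0.272, ATF4 0.288, endothelial 0.289, adipocyte 0.0885 and ribosomal genes 0.0941. With a replicate left out, Erbb2 ran from -0.00412 to 0.0440 and the endothelial list from -0.0463 to 0.0122, neither passing a test. Without knockout replicate 3 the lymphocyte and adipocyte medians were -0.142 and -0.148. Fgfr2 was -0.0873 without hetero replicate 3 and -0.0945 without knockout replicate 3. The fatty acid median was -0.0999 without hetero replicate 1 and -0.00204 without hetero replicate 3. None of these passed either. Frs3 gave no fold and so no alternatives, and slide or scan blocks could not be fitted with 1 slide and 1 scan. Signal over background limited the folds of 286 called genes with a group below background on all its arrays.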

Other observations

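Gene families were grouped by the stem of their symbol after the main results had been seen, and 12 of 253 families with at least 8 tested genes passed camera with the preset correlation, none with an estimated correlation (adjusted p 0.766 to 0.857 for the 12). Keratins rose in 16 of 31 genes and fell in 3 (median 1.79, camera adjusted p = 0.00195). The risers included keratins outside the fixed lists such as Krt23 (3.34 ± 0.11, SE), Krt42 (3.13 ± 0.06), Krt81 (2.48 ± 0.11) and Krt15 (2.13 ± 0.22), while Krt80 fell by 1.17 ± 0.02. Of 10 tested genes of the RASSF family, scaffold proteins with a RAS association domain, 9 rose and 1 fell (median 0.84, camera adjusted p = 0.011): Rassf7 rose by 1.26 ± 0.03 and Rassf4 by 1.91 ± 0.11, whereas Rassf2 fell by 1.55 ± 0.05. Dual-specificity phosphatase genes rose in 15 of 22 and fell in 1 (median 0.42, adjusted p = 0.00478). Myosin heavy chain genes rose in 8 of 10 and fell in 0 (median 0.63, adjusted p = 0.00825). All genes in this part were chosen after their values were seen, and the family medians of this paragraph had the same sign under quantile, median and spike-in scaling.

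Guanylate-binding protein genes, which interferon-gamma induces, were lower in 9 of 9 (median -0.83, adjusted p = 0.00675), a sign that held under the 3 scaling alternatives, with Gbp4 having fallen by 2.47 ± 0.08. C-type lectin genes fell in 10 of 18 and rose in 1 (median -0.30, adjusted p = 0.0241), the median turning to 0.01 with spike-in scaling. The macrophage lectins Clec4e, Clec4n and Clec4d fell by 2.58 ± 0.04, 2.10 ± 0.04 and 1.98 ± 0.03, and Clec3b by 2.93 ± 0.06. Alpha-mannosidase genes, some of which trim N-glycans, were lower in 9 of 9 (median -0.51, adjusted p = 0.011), with Man2a1 and Man1a having fallen by 0.91 ± 0.04 and 0.78 ± 0.05. Olfactory receptor genes, which are not known to be active in mammary cells, did not pass (camera adjusted p = 0.18, adjusted p = 0.923 with an estimated correlation). Their median was -0.23 over 216 tested genes, with 47 lower and 5 higher, and 0.08 with spike-in scaling. Ribosomal protein genes had a list median of -0.22, which turned with quantile and spike-in scaling.

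The tests of chance splits, of even dilution, of an epithelial share and of the H2 region were chosen after the results were seen, and those of scaling and of the DNA around Frs3 before. The call count was 9563 with the real split of the 6 arrays and 0 in the highest of the other splits by limma. At an unadjusted p under 0.05 these were 10252 genes and at most 215. As many genes were called in 1 of the 10 splits, the real one, and 10 splits are too few for a share under 0.05.

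Epithelial genes were higher in the knockout arrays by a median of 3.33 on the log2 scale. Array scaling does not account for it, since over the percentile, quantile, median and spike-in scalings the lowest median was 3.33 and the highest 3.65. A larger share of epithelial cells with the same expression in each, against a rise within the cells, stays open. All 19 members rose, 15 of them within 1 log2 unit of the median, as a change in share may give, yet the SD of their log2 folds was 1.08 against a median SE of 0.041, and expression of some members in other cells could also spread the folds. The genotype of the tumors and chance differences between single tumors or cultures stay among the open explanations, since the labels do not say how many animals each group holds.

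Macrophage genes were lower in the knockout arrays, with a median of -1.81, and array scaling does not account for it: the highest median over the scalings was -1.50. An even dilution of all non-epithelial cells by epithelial cells would lower macrophage and fibroblast genes alike. The macrophage median lay below the fibroblast median of -0.38 by more than chance over the members (difference -1.43, two-sided permutation p = 4.0e-05 over 100000 permutations). Members of a list are not replicates, so this p does not measure spread between samples. Fibroblast genes were mixed, 16 of 22 lower and 4 higher, and expression of some in other cells could narrow their fall. Thy1 rose by 2.29, while Dpt, Pdgfra and Pi16 fell by 1.61, 1.32 and 1.30. An even dilution is thus not excluded. Fewer macrophages in the knockout spheres, or macrophages with less of these transcripts, are further candidate explanations that these data do not separate. Of the list's 3 brightest probes in hetero spheres, whose signals do not rank transcript levels between genes, that of Itgam fell by 0.32 ± 0.03, that of Lyz1 fell by 1.90 ± 0.05 and that of S100a8 rose by 0.63 ± 0.04 (genes chosen after their values were seen), and 1 of the 19 members stands in another list.

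Large changes near Frs3 and in the H2 region, both on chromosome 17, could come from DNA of another strain that travelled with the targeted allele. Of genes chosen after their values were seen, Trem2, Guca1a and B430306N03Rik near Frs3 fell by 1.98, 2.23 and 2.06, and AI661453 rose by 1.10. Trem2 is also a member of the macrophage list, whose median was -1.81. Of genes chosen likewise in the H2 region, H2-D1, H2-K1, C4b and Tnxb fell by 1.57, 1.47, 3.06 and 3.14. There, Ly6g6d was at least 10.2-fold higher by the processed signal. Among the 50 tested genes on each side of Frs3, 12 of 100 changed at least 2-fold. This share lay at percentile 66.1 of 13752 runs of as many neighbouring genes, under the 95th percentile set as the bound. A dense block of changed genes was thus not seen over this span. The genes named above near Frs3 are among its nearest tested neighbours, and no narrower span was tested, so a shorter block stays open. Between H2-K1 and H2-D1, 13 of 73 genes (17.8%) changed at least 2-fold, a share above that of 92.1% of 14319 runs and, with ties, equal to their 95th percentile, and 7 of 60 (11.7%, percentile 59.2) without the antigen presentation list and C4b, Tnxb and Aif1, which had been seen to change. Leaving out changed genes lowers the share, so a strain variant in the H2 region stays open, as does a variant in a single gene or probe.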
